A study of Homo sapiens with 4 samples.

How the data were processed

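Total RNA from 4 cell populations was labelled with Cy3 and hybridised to 1-colour Agilent arrays of 60-mer probes, 1 array for each population: the parental cells, the marrow-derived clone BM2, and CD44-positive and CD44-negative cells sorted from BM2 co-cultured with BM-MSCs. All 4 arrays were on 1 slide and scanned on 1 day. The species of the BM-MSCs is not stated. Co-culture and sorting cannot be told apart, since the 4 arrays hold no co-cultured unsorted sample and no sorted sample without co-culture.

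Per the file headers, the intensity values are the processed signals of Agilent Feature Extraction 10.7.3.1, which subtracted background by spatial detrending, applied a multiplicative detrending, and gave surrogate values to dim spots, with no scaling between arrays. The deposited value table holds the same intensity values for 62976 spots, with a largest relative difference of 0 from the scanner files. Column medians of that signal over spots of gene probes were 43.4 for the parental cells, 49.8 for BM2, 44.2 for the CD44-positive and 48.4 for the CD44-negative cells.

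Control spots were left out, as were 380, 268, 307 and 306 spots marked as outliers on the parental, BM2, CD44-positive and CD44-negative arrays. No spot was saturated. The log2 signal was averaged over the spots of a probe, and the 75th percentile of each array's probes was subtracted; these percentiles were 691, 733, 666 and 709 intensity units. A gene was represented by its brightest probe by the mean of the 4 arrays. A gene was measured in a comparison when that probe was well above background on both arrays. A gene above background on only 1 array gives a lower bound of fold, taken against its own signal on the other array or, if that was dimmer, the lowest signal called well above background there. Probe positions are those of the files, on hg19. Names came from the files and, for 28174 of 50599 probes matched by accession, from a RefSeq table of GRCh38.p14 that was used for names only. Whether a probe lies in an exon or a UTR was not determined, since no annotation of hg19 was at hand. Genes placed on chromosome Y and XIST were left out of every named result.

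The 4 comparisons, with 1 array per group, were BM2 against parental cells, CD44-negative against CD44-positive cells, and each sorted population against BM2. Genes at least 2-fold apart were counted. The spot error of a difference combines, for the 2 arrays, the SD of repeated spots of probes of like brightness, whose medians lay between 0.0552 and 0.0574 on the log2 scale. It covers spot noise and not variation between cultures.

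The 24 gene lists, the comparisons, the rule for named genes and the first 7 of the other settings below were fixed before the data were examined. The lists were G2/M and mitosis, DNA replication and S phase, cell cycle inhibitors and dormancy-associated genes, breast cancer stem cell markers, mesenchymal state genes, epithelial genes, bone metastasis-associated genes, marrow stromal, blood, endothelial and adipocyte markers, interferon response, hypoxia and glycolysis, NF-kappaB and inflammatory genes, matrix-degrading proteases and inhibitors, cholesterol synthesis, unfolded protein and ATF4 response, immediate early and heat shock genes, TGF-beta and YAP target genes, ABC drug efflux transporters, cytosolic ribosomal proteins, mitochondrial oxidative phosphorylation, replication-dependent histones, and antigen presentation. Of 667 list members, 4 were not found on the array. The median difference of each list was placed among 10000 random lists of the same size, drawn from named genes in 20 bins of expression. A list outside the central 99% of these was singled out, a limit chosen after the values had been seen. Members of a random list were drawn independently, so its spread leaves out that genes of a list may move together between cultures. A place outside this range is therefore no test of a difference between groups.

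Named genes were, for each comparison, the 10 highest and the 10 lowest differences among genes with a symbol whose other measured probes differed in the same direction, and the 4 largest bounds in each direction. CD44, CD24 and MARCKS were always named. From each list described, up to 4 members with the largest differences of at least 2-fold were named, or else the 2 brightest members. The MHC class II, MAGEA and CSAG, intronic, nuclear RNA and chromosome groups were chosen after their values had been seen.

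The other settings tried were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), quantile normalization, scaling on the median of detected probes, the deposited values without scaling, genes detected on all 4 arrays, no filter on dim probes, and the mean of a gene's probes. Removal of the trend with probe GC in 20 bins, scaling on the 7 bright E1A control probes and comparison of the sorted populations with the parental cells were added after the data had been seen. The overlap of the comparisons against BM2 was set beside 100 simulations of spot noise with the shared array. The procedure was tested on simulated data for BM2 against parental cells over 18274 genes: 99% of genes shifted by 1.5 on the log2 scale and 100% of those shifted by 3 were recovered, and 0.0166% of unshifted genes passed 2-fold. A simulated list of 30 genes lay at percentile 52.8 unshifted and at percentile 100 when shifted by 0.5. The simulated arrays held spot noise alone, without variation between cultures or extracts, so 0.0166% is not an error rate of the 2-fold counts. Analyses used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.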

Results

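RNA of a human breast cancer cell line and of derivatives recovered from bone marrow was hybridised to 4 one-colour arrays, 1 array for each of 4 groups. MDA-MB-231 is a triple-negative, mesenchymal-like breast cancer line, and the parental cells were its D3H2LN subline carrying luciferase and green fluorescent protein. BM2 was a clone grown from a tumour cell recovered from the marrow of a mouse on day 10 after intracardiac injection. The 2 remaining samples were BM2 cells grown together with BM-MSCs and then sorted by flow cytometry into CD44-positive and CD44-negative populations, CD44 being a surface receptor used as a cancer stem cell marker. Of 50599 probes on the array, 25339 were well above background for the parental cells, 28120 for BM2, 26907 for the CD44-positive cells and 27573 for the CD44-negative cells. Groups had no replicate arrays, so no test could be made, no p-value is given, and "higher" and "lower" describe single arrays. Values are log2 differences of normalised intensity, and the error after ± is the spread of repeated spots of other probes at like brightness (n = 1 array per group), which leaves out variation between cultures. The number of arrays limits the precision.

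The transcript of the sorting marker differed little between the 4 arrays. The brightest CD44 probe (chromosome 11, 35253812 to 35253871, on hg19 as all positions here) had a level of 6.51 log2 units above the array's 75th percentile in parental cells, 6.32 in BM2, 6.25 in CD44-positive cells and 6.18 in CD44-negative cells. CD44-negative cells were at -0.06 ± 0.06 against CD44-positive cells, and this sign turned with other scalings, to 0.13 with quantile normalization, 0.03 without scaling and 0.28 with scaling on the E1A control probes. The other measured CD44 probe differed by -0.14 between the sorted populations and by 0.42 between BM2 and parental cells, where the brightest probe gave -0.19 ± 0.06. CD24, a surface glycoprotein used beside CD44 to define breast cancer stem cells, differed by -0.06 ± 0.06 between the sorted populations and by -0.79 ± 0.06 between BM2 and parental cells, from a probe whose listed position is not that of CD24 itself. MARCKS, a protein kinase C substrate at the membrane, stood at -0.35 ± 0.06 in BM2 against parental cells and, in CD44-negative against CD44-positive cells, at -0.13 ± 0.06, and the signs of CD24 and MARCKS in the latter turned with the E1A scaling.

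The first comparison asked how the marrow-derived clone differed from the cells that had been injected. Cholesterol synthesis genes were higher: 13 of 24 were at least 2-fold higher in BM2, none was 2-fold lower, and the list median was 1.01, above all 10000 random lists matched on expression. The largest difference was that of HMGCS1 (chromosome 5, 43290117 to 43290176), which makes HMG-CoA, at 2.30 ± 0.07, and MSMO1 was higher by 1.60. Genes of antigen presentation were also higher, with a list median of 0.35 above all random lists and 6 of 21 members at least 2-fold higher. All of these 6 belonged to the MHC class II pathway, led by HLA-DPA1 (chromosome 6, 33032848 to 33032907) at 2.70 ± 0.09, HLA-DPB1 at 1.84, HLA-DRB1 at 1.62 and HLA-DRA at 1.58.

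Single genes differed by more than any list. SPP1 (chromosome 4, 88903920 to 88903979), which encodes the bone matrix protein osteopontin, was 8.56-fold higher in BM2 (spot error 0.13 on the log2 scale). The highest difference belonged to the long non-coding RNA LETR1 at 5.29 ± 0.22, followed by RAB37 at 3.30, SETBP1 at 3.28, PAEP at 3.25 and the glycolytic aldolase ALDOC at 3.11. MAGEA1, a cancer-testis antigen, was at 3.09, KCNIP4 at 2.91 and TMEM244 at 2.84. In the other direction, the long non-coding RNA UCA1 (chromosome 19, 15946035 to 15946092) was 109.6-fold lower in BM2, at -6.78 ± 0.11. CETN2, a centrin of the centrosome, was at -6.18 ± 0.22, the protease inhibitor CST6 at -4.19, DIO2, which activates thyroid hormone, at -4.02 and HCLS1 at -3.68. KCTD7 stood at -4.19 and LIMS4 at -4.06. In BM2 the levels of CETN2, KCTD7 and LIMS4 were -5.00, -4.92 and -5.00, near the lowest signal called well above background there, -5.38. LETR1 was likewise at a level of -4.37 in parental cells, where that lowest signal was -4.75. The sizes of these differences are therefore uncertain. CETN2 also lies on chromosome X, whose genes were lower as a group in BM2. RBBP5 was at -4.37 on its brightest probe and at -0.03 on its other probe, so its probes disagreed in size. Probes of MAGEA1 and of the HLA genes have near-identical copies elsewhere, which leaves their assignment uncertain. Among genes well above background on BM2 alone, TLR4 was at least 22.8-fold, SLC4A5 at least 28.5-fold, MAGEA11 at least 22.1-fold and FKBP10 at least 13.4-fold higher. ACSM6 was at least 70.5-fold, MESTIT1 at least 41.6-fold, CPE at least 40.8-fold and PPDPFL at least 34.9-fold lower, being above background on the parental array alone.

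Hypoxia and glycolysis genes had a median of 0.30, above all random lists, with 3 of 27 at least 2-fold higher, namely ALDOC, NDRG1 at 1.49 and the glucose transporter SLC2A3 at 1.27. Matrix proteases and their inhibitors had a median of 0.27, at percentile 99.86, with MMP3 at 1.38, MMP9 at 1.05 and SERPINE2 at 1.20. NF-kappaB and inflammatory genes had a median of -0.33, at percentile 0.22, with 5 of 25 at least 2-fold lower, among them BIRC3 at -1.93 and IL32 at -1.78, and 2 higher, CXCL1 at 1.68 and PTGS2 at 1.48. Replication-dependent histone genes had a median of -0.77, below all random lists, with H2AC8 at -1.82, H1-2 at -1.74 and H1-3 at -1.42. Interferon response genes lay inside the central 99% of random lists at a median of 0.14, with 4 of 34 at least 2-fold lower and 4 higher: BST2, which tethers budding virus, was at -4.41, IFI27 at -4.17 and HERC6 at -2.65, against OASL at 1.54.

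The lists of bone metastasis-associated genes (median 0.09, percentile 88.6) and breast cancer stem cell markers (0.02, percentile 80.9) lay inside the range of random lists. Single members nevertheless differed, with SPP1 highest, LOX at 1.42, the Notch ligand JAG1 at 1.20, NOTCH3 at 2.46, the BMP antagonist NOG at -1.20 and LGR5 at -1.90. Cell cycle inhibitors and dormancy-associated genes were at 0.16 (percentile 99.27), mesenchymal state genes at 0.14 (percentile 99.50) with LOX, FN1 and COL6A1 at least 2-fold higher, and ABC drug efflux transporters at 0.27 (percentile 92.5) with ABCC3, ABCB6 and ABCA1 at least 2-fold higher, though ABCC3 was at 0.28 on its other probe. DNA replication and S phase genes (median -0.15, percentile 42.5), G2/M and mitosis genes (-0.22, percentile 12.5), ribosomal protein genes (-0.27, percentile 4.12), oxidative phosphorylation genes (-0.23, percentile 18.4) and TGF-beta and YAP targets (-0.25, percentile 5.22) also lay inside it. Genes on chromosome X, a group chosen after the values were seen, had a median of -0.54 over 610 genes, or -0.48 relative to all genes, while the autosomes lay between -0.20 and 0.20 on the latter scale. Nuclear and ribosomal RNAs, also chosen after the values were seen, differed between these arrays too: the 18S ribosomal RNA probe was at -1.58, MALAT1 at a median of -0.66 over 8 probes, NEAT1 at 0.47 over 5 probes, and transcripts annotated as intronic at 0.51 (percentile 99.56), with 3 of 17 at least 2-fold higher. The NEAT1 probes ran from -0.41 to 1.39, so its sign depended on the probe. In the blood cell list, at 0.11 (percentile 77.4), the monocyte marker CD14 was at 2.55 and CD33 at 1.27, or 0.45 on its other probe.

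In all, 772 of 18265 measured genes were at least 2-fold higher in BM2 and 599 at least 2-fold lower, and the median over all genes was -0.06. Genes above background on 1 of the 2 arrays added 401 higher and 606 lower with a bound of at least 2-fold. The totals were 1173 and 1205, so with these bounds the lower genes were slightly more. Such totals rest on the detection limits of the arrays. In all, 2617 genes were above background on BM2 alone and 716 on the parental array alone, and the lowest signals so called were -5.38 and -4.75. With normexp background correction these counts were 361 and 343, and with no filter on dim probes 2884 and 2549. Scaling on the E1A control probes, which differed by -0.13, moved the median over all genes to 0.07 and the share of higher genes among those 2-fold apart from 56.3% to 69.8%.

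**Figure D1:**
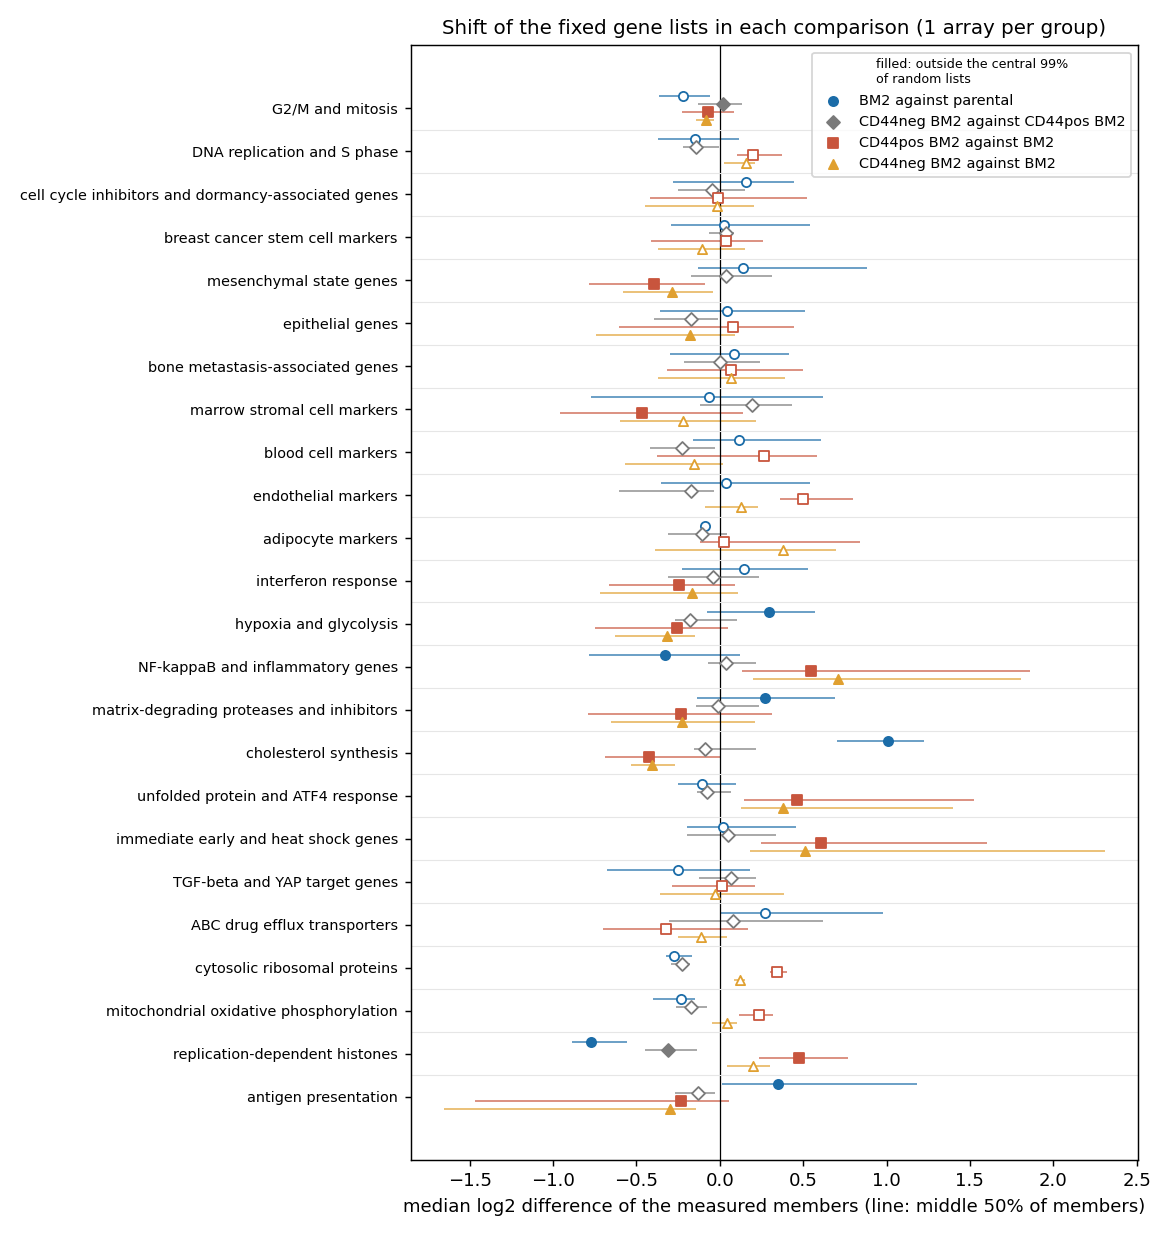
Horizontal axis, median log2 difference of each fixed gene list over its measured members, with lines for the middle 50% of members and a colour and symbol for each of the 4 comparisons (1 array per group). Filled symbols lie outside the central 99% of 10000 random lists matched on expression. Cholesterol synthesis lies at 1.01 in BM2 against parental cells and at -0.43 and -0.41 in the sorted populations against BM2, while the immediate early list lies at 0.61 and 0.51 in the latter.

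The second comparison asked how CD44-negative cells differed from CD44-positive cells, both sorted from co-cultured BM2. The gene lists were close together: 22 of 24 lay inside the central 99% of random lists, and no list had more than 2 members at least 2-fold apart in either direction. The signs of 16 of the 24 medians turned under another scaling, so most directions here depended on it. This number was 3 for BM2 against parental cells, and 8 and 2 for CD44-positive and CD44-negative cells against BM2. Breast cancer stem cell markers had a median of 0.04 (percentile 87.8) with none of 21 members 2-fold apart. Epithelial genes were at -0.17 (percentile 7.06), or 0.17 with the E1A scaling, with KRT18 at -0.30 and KRT19 at -0.53. The mesenchymal state genes were at 0.04 (percentile 96.1), with the intermediate filament gene VIM at -0.25 and the receptor kinase gene AXL at -0.22, and the signs of KRT18, VIM and AXL also turned with the E1A scaling. Cell cycle inhibitors and dormancy-associated genes were at -0.05 (percentile 57.8), or 0.30 with the E1A scaling, with none of 27 2-fold apart.

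G2/M and mitosis genes, at 0.02 and percentile 99.71, and replication-dependent histones, at -0.31 and percentile 0.23, were outside that range, with no member of either list 2-fold apart. The sign of the G2/M median turned to -0.02 once the trend with probe GC was removed, and that of the histone median turned to 0.04 with scaling on the E1A control probes. Among single members, the membrane-bound metalloproteinase MMP14 was higher in CD44-negative cells at 1.06 ± 0.07 and the immediate early gene NR4A3 at 1.34 ± 0.10. The endoplasmic reticulum stress gene SDF2L1 was lower at -1.22 ± 0.06. In the interferon list, DDX60 stood at -1.79, OAS2 at -1.01 and RSAD2 at 1.14.

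Single genes outside the lists differed by more. HAP1 (chromosome 17, 39879781 to 39879840), which encodes a huntingtin-binding protein, was at -4.24 ± 0.28 in CD44-negative cells and BMPR1B, a BMP receptor gene, at -3.83 ± 0.28. RIBC1 was at -3.30, ELAC1 at -3.14, the macrophage mannose receptor gene MRC1 at -3.14, CIMAP3 at -2.72, the interleukin-1 receptor antagonist IL1RN at -2.71, CDO1 at -2.52, CLEC2L at -2.50 and TRA2A, a splicing factor gene, at -2.41. Higher were VMO1 at 2.85 ± 0.20, MAML2, a Notch coactivator gene (chromosome 11, 95712375 to 95712434), at 2.76 ± 0.20, PRR15 at 1.91, ALPI at 1.89, SCN8A at 1.82, MCOLN3 at 1.78 (0.71 on its other probe) and TCF15 at 1.77, with PRR5-ARHGAP8 at 2.47, SDIM1 at 1.97 and the pseudogene AQP7P1 at 1.82. Several of these genes were near the lowest signal called well above background, -5.20 in CD44-negative and -5.08 in CD44-positive cells. HAP1, CLEC2L, CIMAP3, IL1RN and MRC1 had levels of -5.06, -5.02, -4.86, -4.84 and -4.82 in CD44-negative cells. SDIM1, SCN8A, ALPI and VMO1 had levels of -4.99, -4.93, -4.83 and -4.69 in CD44-positive cells. The sizes of their differences are thus uncertain. PTOV1-AS1 was at least 64.8-fold, ADCK1 at least 42.1-fold, PARP15 at least 23.6-fold and ITIH1 at least 20.2-fold lower in CD44-negative cells, where they were not well above background. RASGEF1C was at least 13.5-fold, KRT36 at least 13.3-fold, KLHL38 at least 12.5-fold and DACH2 at least 11.8-fold higher. PTOV1-AS1, ADCK1 and PARP15 were not well above background in BM2 either, where HAP1 and BMPR1B stood at levels of only -4.70 and -4.69. Among the BM2-derived arrays, these genes thus stood out on the CD44-positive array, and their levels in parental cells are not given here. In the same way, and among the same arrays, RASGEF1C, KRT36 and KLHL38, not well above background in BM2, stood out on the CD44-negative array.

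Nuclear and ribosomal RNAs, chosen after the values were seen, differed between these 2 arrays. Over the 8 probes of MALAT1, a nuclear long non-coding RNA, the median difference was 1.57 (1.06 to 2.27), and over the 5 probes of NEAT1, which builds nuclear paraspeckles, it was 1.26 (1.14 to 1.76), both higher in CD44-negative cells. Transcripts annotated as intronic had a median of 0.93, with 7 of 16 at least 2-fold higher. The 18S ribosomal RNA probe was at -2.17. Across genes the difference followed probe GC content (Pearson r = -0.244 over 19221 genes, which are not independent replicates), from a median of 0.05 at a GC content of 35% or less to -0.25 at 55% or more. The E1A control probes differed by -0.34 after scaling.

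In all, 335 of 19221 genes were at least 2-fold higher in CD44-negative cells and 242 at least 2-fold lower, the fewest of the 4 comparisons, and genes above background on 1 array added 333 and 377 with such a bound. These counts were 86 and 102 with normexp, 1911 and 1875 with no filter on dim probes, and 924 and 92 with scaling on the E1A probes, which moved the median over all genes from -0.04 to 0.30. With the E1A scaling they were no longer the fewest, since CD44-negative cells against BM2 had 440 higher and 465 lower. The share of higher genes, 58.1%, was 71.3% in the unscaled deposited values and 90.9% with the E1A scaling.

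The third question was how each sorted population differed from unsorted BM2, a comparison in which co-culture and sorting go together. Immediate early and heat shock genes were higher in both sorted populations: 11 of 30 were at least 2-fold higher on each array and none 2-fold lower, with medians of 0.61 in CD44-positive and 0.51 in CD44-negative cells, both above all random lists. ARC, a neuronal immediate early gene (chromosome 8, 143692579 to 143692638), was at 5.61 ± 0.22 and 5.67 ± 0.22, the inducible chaperone gene HSPA6 at 4.82 and 5.54, HSPA1A at 3.94 and 4.30, FOSB at 3.77 and 4.33 and FOS at 3.11 and 3.38, in that order of populations. EGR4 was at 3.31 and 3.22, and EGR1 at 3.38 in CD44-negative cells. The stress-induced growth arrest gene GADD45G was at 4.43 and 4.51. HSPA1A has a near-identical copy, so which of the copies its probe measured is uncertain.

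Inflammatory and stress genes were higher on both arrays as well. NF-kappaB and inflammatory genes had medians of 0.55 and 0.71, above all random lists, with 9 and 10 of 25 at least 2-fold higher and 2 lower on each array. The cytokine gene IL24 was at 3.22 and 3.06, the NF-kappaB subunit gene RELB at 2.58 and 2.38 and TNFAIP3, an inhibitor of the pathway, at 2.18 and 2.71. CXCL3 was at 2.08 in CD44-positive cells and BIRC3 at 2.52 in CD44-negative cells. Unfolded protein and ATF4 response genes had medians of 0.46 and 0.38, above all random lists, with 9 of 29 at least 2-fold higher and 1 lower on each array, the higher ones including ATF3, which was 7.53-fold and 8.58-fold higher on its brightest probe, with log2 differences down to 0.80 and 0.97 on its other probes, DDIT3 at 2.11 and 2.08, PPP1R15A at 2.03 and 1.95 and asparagine synthetase (ASNS) at 2.09 and 1.89. In CD44-positive cells, BMPR1B at 4.27, HAP1 at 3.88 and SPRR2A at 3.23 were among the 10 highest, and in CD44-negative cells SPX at 3.80 and ARL14 at 3.55 were. NBR2 was at 4.19 in CD44-positive cells on its brightest probe and at 0.11 on its other probe. PTOV1-AS1, which was not well above background in BM2, was at least 83.2-fold higher in CD44-positive cells, and RASGEF1C at least 16.7-fold higher in CD44-negative cells.

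Several genes that stood higher in BM2 than in parental cells were lower in the sorted populations than in BM2. The single BM2 array enters both comparisons with opposite signs, so a deviation of that array alone would give this, and no value expected without a difference was computed. SPP1 was at -4.27 ± 0.20 and -3.66 ± 0.27 against BM2, NOTCH3 at -2.96 and -2.78, SETBP1 at -3.69 in CD44-positive cells and LETR1 at -4.19 in CD44-negative cells. The level of SPP1 in CD44-positive cells was -4.69, near the lowest signal called well above background there, -5.08. The size of its difference there is thus uncertain. The guanylate-binding protein gene GBP2 was at -3.99 and -3.33, the retinol transporter gene STRA6 at -3.43 and -4.09 and PAK6 at -2.92 and -3.43, while ITGA1 at -3.32 and RNASE1 at -3.05 were among the 10 lowest in CD44-positive cells and SLPI at -3.27 and CALHM3 at -3.21 in CD44-negative cells. JAKMIP3 was at least 16.2-fold and 17.6-fold lower, since it was not well above background on either sorted array. The genes from GBP2 to JAKMIP3 were named for their differences against BM2. Whether they were higher in BM2 than in parental cells is not given here. Antigen presentation genes had medians of -0.23 and -0.30, both below all random lists, and all 7 measured MHC class II pathway genes in CD44-positive cells and all 8 in CD44-negative cells were at least 2-fold lower, a subset named after the values were seen. HLA-DPA1 was at -2.84 and -3.30, HLA-DRA at -2.31 and -2.21 and HLA-DMB at -1.78 and -2.24. HLA-DPB1 was at -2.56 and -3.04 on its brightest probe, and its other probes reached 0.29 and -0.02. Cholesterol synthesis genes were at -0.43 and -0.41, below all random lists, with MSMO1 at -1.15 in CD44-positive cells. Hypoxia and glycolysis genes were at -0.25 and -0.32, below all random lists, with ALDOC at -1.57 and -1.81.

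**Figure D2:**
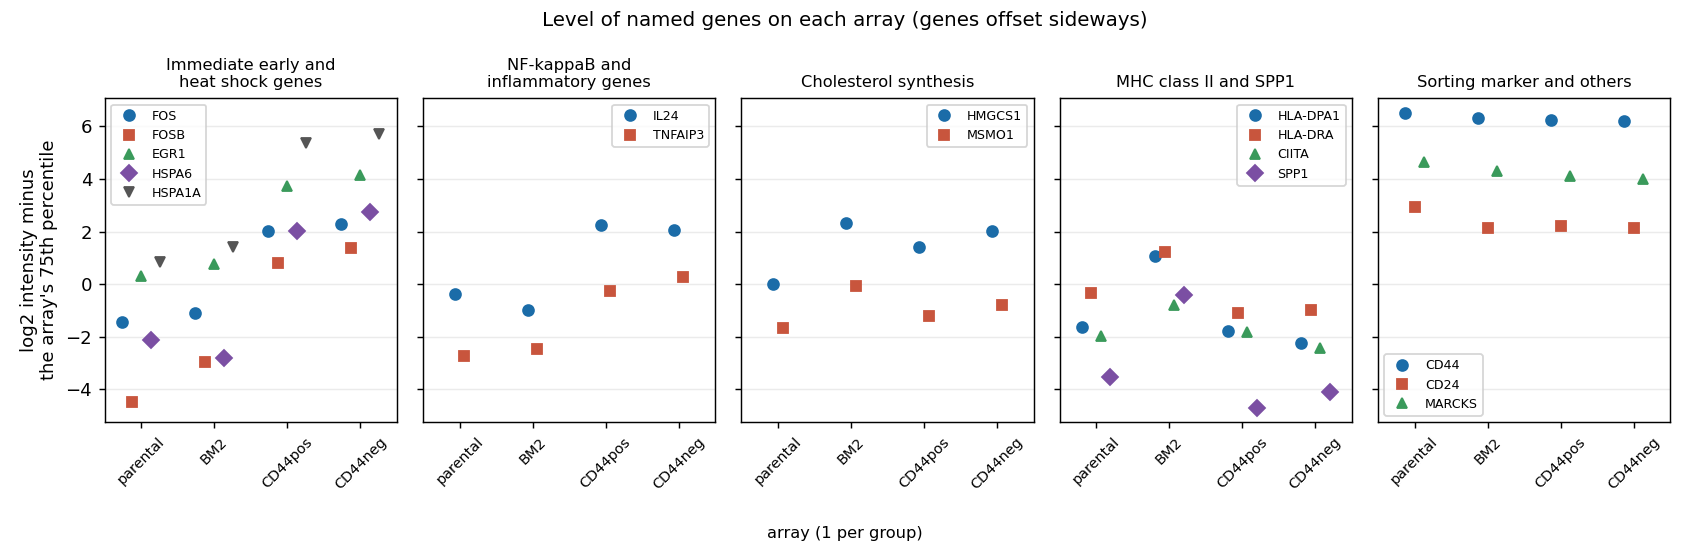
Vertical axis, log2 intensity minus the array's 75th percentile, and horizontal axis, the 4 arrays (1 per group), with a symbol for each gene. FOS lies at -1.45 in parental cells, -1.10 in BM2, 2.01 in CD44-positive and 2.29 in CD44-negative cells, whereas CD44 lies between 6.18 and 6.51 on all 4 arrays.

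Mesenchymal state genes were at -0.40 and -0.29, below all random lists, with the calcium-binding S100A4 at -2.43 and -2.66 and COL6A1 at -1.14 and -1.31. SNAI1, a repressor of epithelial genes in the same list, went the other way at 2.42 and 2.75, and against parental cells the list was at -0.23 (percentile 0.31) and -0.07 (percentile 47.3). Matrix proteases and inhibitors were at -0.23 and -0.22 (percentile 0.06 on each), with TIMP3 at -1.77 and -1.89, while the largest difference of the list went the other way, the metalloproteinase MMP3 at 2.45 and 2.80. Interferon response genes were at -0.25 (percentile 0.06) and -0.17 (percentile 0.26), with IFITM1 at -1.83 and -2.72 and IFIT1 at -1.48 and -1.59. In the same list 1 member on each array was at least 2-fold higher, DDX60 at 1.62 in CD44-positive and RSAD2 at 1.33 in CD44-negative cells. G2/M and mitosis genes were at -0.07 and -0.09, at percentiles 0.01 and 0.08, with none of 32 members 2-fold apart. Cell cycle inhibitors and dormancy-associated genes were inside the central 99% at -0.01 (percentile 9.5) and -0.02 (percentile 15.2), the latter 0.01 with the E1A scaling, with GADD45A at 1.63 and 1.84 and GADD45B at 1.67 and 1.46, against BHLHE40 at -1.27 and BMPR2 at -1.27 in CD44-positive and DDIT4 at -1.19 in CD44-negative cells. TGF-beta and YAP targets were inside it too, at 0.02 (percentile 8.65; -0.12 without scaling) and -0.03 (percentile 8.49), with ID2 at 1.56 and 1.80 against SMAD6 at -1.61 and -1.52 and LTBP1 at -1.13 and -1.23. Epithelial genes were at 0.08 (percentile 40.2), a sign that turned to -0.06 without scaling, and -0.18 (percentile 0.33), and replication-dependent histones at 0.48 (percentile 99.97) and 0.20 (percentile 97.7).

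Markers of other cell types that the cultures could hold were set beside these lists. Marrow stromal cell markers had medians of -0.47 (percentile 0.205) and -0.22 (percentile 1.59), with none of 15 and 17 measured members at least 2-fold higher and NGFR at -3.07 and -3.57, COL6A3 at -2.65 and -1.97 and THBS2 at -1.40 and -1.13. Members above background on 1 array of a comparison do not enter these values. COL3A1 was so on the CD44-positive array and not in BM2, and DCN and LUM in BM2 and on neither sorted array. The endothelial list was at 0.50 (percentile 98.9) and 0.13 (percentile 75) over 6 measured members, with VWF at 1.61 and 2.15 on its brightest probe and -0.10 and 0.35 on its other probe, and the adipocyte list at 0.03 (percentile 45.9; -0.11 without scaling) and 0.38 (percentile 99.38). The blood cell list was at 0.26 (percentile 96.3; -0.05 with the E1A scaling) and -0.15 (percentile 7.61), with CD14 at -2.35 and -2.78 and ITGAM at 1.58 and 1.88. On the CD44-positive array, MALAT1 was at -1.11 and NEAT1 at -1.20 against BM2, medians over the same 8 and 5 probes, the 18S probe at 2.59, the intronic transcripts at -0.81 with 6 of 17 at least 2-fold lower, and the difference followed probe GC (Pearson r = 0.162 over 19260 genes). On the CD44-negative array these values were 0.57, 0.26, 0.42, 0.19 and -0.0251, with single NEAT1 probes from -0.32 to 0.54.

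Of 18985 genes measured in both comparisons against BM2, 224 were at least 2-fold higher and 310 at least 2-fold lower in both sorted populations, and 3 were 2-fold apart in opposite directions. The differences correlated across genes at Pearson r = 0.685, against 0.455 in 100 simulations with the shared BM2 array, which held spot noise and no variation between cultures, and their covariance was 0.177 against a simulated 0.00775. The BM2 array enters both comparisons and could not be split, and its own deviations add to the shared part.

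Against BM2, 591 of 19260 genes were at least 2-fold higher and 641 lower in CD44-positive cells, and 419 of 19586 were higher and 495 lower in CD44-negative cells. Genes above background on 1 array added 490 higher and 334 lower with a bound of at least 2-fold in CD44-positive cells, and 409 and 304 in CD44-negative cells. The totals were 1081 higher and 975 lower, and 828 and 799, so the more frequent direction turned in both. These totals too rest on the detection limits of the arrays. For CD44-positive cells, 858 genes were above background there alone and 1629 on BM2 alone. For CD44-negative cells these numbers were 926 and 1317. With normexp the counts were 280 and 247 in CD44-positive and 188 and 222 in CD44-negative cells, and with no filter on dim probes they were 2410 and 2384, and 2076 and 2179. For CD44-positive cells the share of higher genes, 48.0%, was 31.5% in the unscaled deposited values and 17.1% with scaling on the E1A probes, where the counts were 302 and 1468 and the median over all genes moved from 0.08 to -0.23.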

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

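The tests of the patterns weighed here were all chosen after the results had been seen. MAML2, a Notch coactivator gene, was at -1.35 on the CD44-positive array and at 1.42 on the CD44-negative array against BM2, so it differed in direction between the sorted populations, a difference that was not tested. It was 1 of 3 genes 2-fold apart in opposite directions, the others being features without a gene symbol. Among 96 control probes for ERCC RNAs, which enter no comparison, ERCC-00113_271 was above background in 97.1% of 35 spots on the CD44-positive array, against 5.71%, 5.71% and 8.57% on the parental, BM2 and CD44-negative arrays. ERCC-00148_99 was above background in 100% of its spots on the CD44-negative array, and in 82.9%, 97.1% and 97.1% on the parental, BM2 and CD44-positive arrays.

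Immediate early and heat shock genes were higher on both sorted arrays than on BM2. A BM2 array that stood apart is argued against, since the list was also above all random lists against parental cells, with medians of 0.61 and 0.37 in CD44-positive and CD44-negative cells and 11 of 29 members at least 2-fold higher in each. The stromal marker medians, the higher of which was -0.22, cannot show markers absent from BM2, since only members above background on both arrays enter. Of all 34 markers, 21 were above background in BM2, against 16 in CD44-positive and 19 in CD44-negative cells. Over all probes the share above background had the same order, at 55.6%, 53.2% and 54.5%. Part of the fall in the marker counts may thus follow the detection limits. COL1A2 and POSTN were not well above background on either sorted array, and COL1A1 stood below its BM2 level. COL3A1 went the other way, being above background on the CD44-positive array alone. These values argue against a large carry-over of human marrow stromal cells through the sort, and a small one stays open. Stromal cells of another species stay open, since the species of the BM-MSCs is not stated and the probes are human. Handling during the sort and co-culture cannot be told apart, since 0 arrays held co-cultured cells that were not sorted, so either may have raised these genes.

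Transcripts annotated as intronic were higher on the CD44-negative than on the CD44-positive array, with a median of 0.93. Probe GC content is argued against as the whole cause, since the median was 0.86 after the GC trend was removed. From the intronic transcripts, which of the arrays stood apart cannot be told. CD44-positive and CD44-negative cells were at -0.81 and 0.19 against BM2 but at -0.36 and 0.63 against parental cells. Against parental cells, MALAT1 was at -1.76 and -0.14, and the correlation with probe GC was 0.128 and -0.0473. In these 2 measures the CD44-positive array lay further from the parental array. NEAT1, at -0.54 and 0.71, did not show this. Ribosomal RNA content or RNA quality stays open, since the 18S probe differed by -2.17 between the arrays and 4 arrays are too few to relate these measures. The 18S probe and the intronic transcripts also went opposite ways in BM2 against parental cells, at -1.58 and 0.51. They did so in CD44-positive cells against BM2, at 2.59 and -0.81, but not in CD44-negative cells against BM2, at 0.42 and 0.19. Against parental cells they went opposite ways in CD44-positive cells, at 1.02 and -0.36, and in CD44-negative cells, at -1.16 and 0.63. These comparisons share arrays and are not independent. A biological difference between the CD44 populations was not tested and stays open too.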

How the results depend on the processing

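The alternatives with scaling on the E1A control probes and with removal of the probe GC trend were chosen after seeing the data. All 232 named differences of at least 2-fold kept their direction under the 8 other settings in which each was measured, as did 199 of 199 with genes detected on all 4 arrays. For several settings this was fixed in advance. No filter and detection on all 4 arrays use the same values. Median scaling, E1A scaling and the unscaled values only add a constant per comparison, too small to turn such a difference. A constant also leaves a list's place among random lists almost unmoved. Of the 232, 197 were still at least 2-fold apart with normexp, 224 with E1A scaling, and 227 to 232 under the other 6. Between 30 and 35 of 96 list medians lay outside the central 99% of random lists under the alternatives, against 31 in the values reported, and 27 to 31 were shared with these. Counts of higher and lower genes with normexp were 361 and 343 in BM2 against parental cells, 86 and 102 in CD44-negative against CD44-positive cells, 280 and 247 in CD44-positive cells against BM2, and 188 and 222 in CD44-negative cells against BM2. With no filter on dim probes they were, in the same order, 2884 and 2549, 1911 and 1875, 2410 and 2384, and 2076 and 2179. With E1A scaling they were 924 and 92 in CD44-negative against CD44-positive cells and 302 and 1468 in CD44-positive cells against BM2, from a shift of every gene by the difference of these probes. Genes 2-fold apart in the same direction in both sorted populations numbered 534, against 269 with normexp and 2095 with no filter. In CD44-negative against CD44-positive cells, the G2/M median was -0.0205 with the GC trend removed and the histone median 0.0353 with E1A scaling. The cause was not tested for normexp, the filter on dim probes or the G2/M list. An alternative with the slide as a block was not run, since 1 slide held 1 array per group. Signal over background limits the dimmest genes, since between 50.1% and 55.6% of probes were well above background on the 4 arrays.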

Other observations

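The tests and comparisons in this part were all chosen after the results had been seen. The sorted populations were also set against the parental array, which BM2 was compared with as well, so a deviation of that array alone would appear in all of these values. Cholesterol synthesis genes had medians of 0.45 in CD44-positive and 0.55 in CD44-negative cells, above all random lists, with 5 and 2 of 24 at least 2-fold higher. Hypoxia and glycolysis genes were at -0.05 and -0.19 and matrix proteases and inhibitors at 0.01 and -0.24, inside the central 99% of random lists, although both lists were above that range in BM2. Cancer-testis genes of the MAGEA and CSAG families were at least 2-fold higher than in parental cells for 7 of 7 measured members in BM2 and in both sorted populations, with medians of 2.58, 2.61 and 2.44, and at 0.03 and -0.10 in the sorted populations against BM2, where 9 were measured. These families have near-identical copies, so single members are uncertain.

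Unfolded protein and ATF4 response genes were at 0.35 (percentile 99.98) and 0.23 (percentile 99.96) against parental cells, NF-kappaB genes at 0.21 (percentile 96.7) and 0.40 (percentile 99.98), G2/M genes at -0.39 and -0.34, below all random lists, and TGF-beta and YAP targets at -0.37 in each (percentiles 0.02 and 0.04). MHC class II genes, higher in BM2 at a median of 1.42 over 8 genes, were at -0.72 and -0.62 in the sorted populations against parental cells.

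Genes on chromosome X were lower on the BM2 array than on the parental array, at -0.48 relative to all genes, and were at -0.55 and -0.52 on the CD44-positive and CD44-negative arrays. Probe GC content is argued against, since the shift was -0.48 after the GC trend was removed, and so are a few genes with large differences, since 78.9% of 610 X genes lay below the all-gene median. A shift arising in co-culture or sorting is argued against, since the larger shift of the sorted arrays against BM2 was -0.0256. A clone with a lower dosage of X may give this pattern, but it cannot be told apart from a parental array that stands apart, since there were 0 further parental arrays.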
